A study of Mus musculus with 30 samples.

How the data were processed

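RNA of fetal lung and fetal liver was measured on Affymetrix mouse expression arrays, 15 arrays per tissue. Per the labels, CD-1 dams received PFOS as the potassium salt by mouth, in 0.5% Tween 20, from gestation day 1 to 17, and tissues were collected on gestation day 18. RNA of 3 fetuses was pooled per litter, each array is 1 litter, and 5 litters per tissue were measured at each of 0, 5 and 10 mg/kg/day. RNA was used only with an integrity number of at least 8, per the labels' protocols.

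The deposited values are log2 probe set summaries made with RMA, a method that corrects background, normalizes between arrays and summarises the probes of a set, per the submitters' processing notes. The RMA version and which arrays were normalized together are not given in the sources used here. Mean log2 levels ran from 5.09 to 5.10 over the lung arrays and from 5.08 to 5.09 over the liver arrays. RMA compresses changes of dim probe sets, so changes from a dim level can be understated. Normalization between arrays assumes that most probe sets do not change.

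Of 45101 probe sets, 34945 have 1 gene symbol in the platform annotation, 932 have several and 9160 have none, and 64 are controls of the array maker. Genes were named from probe sets with 1 symbol, which gave 18193 genes, each taken from its probe set with the highest mean over all arrays. A gene was tested in a tissue where its probe set lay above the 40th percentile of all probe sets on at least 5 of the 15 arrays.

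Each tissue was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per dose and an empirical Bayes estimate of the spread, and figures were drawn with matplotlib 3.10.9 and numpy 2.4.6. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The difference between tissues was tested in 1 fit of all 30 arrays as the difference of the changes. Changes shared by both doses were set beside 100 simulations of unchanged groups against the same controls, and beside values with the controls split. The 53 gene lists were written before the data were examined, and 970 of their 1059 entries matched a gene. A list with at least 3 tested genes was tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation. The list symbols Cyr61, Atp5f1 and Cyp2c44 were matched to their current names Ccn1, Atp5pb and Cyp2c23, a step added after the data were examined.

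The rule for named genes was fixed before the data were examined. For each tissue and dose it takes the 10 largest rises and falls among called genes with all 5 exposed litters on 1 side of the control mean, except symbols of clones and predicted genes. It adds for each list up to 4 called members by size of change, or else up to 2 members with the smallest p, and it adds Ehhadh, Cyp4a14, Pdk4, Fgf21, Cyp2b10, Cyp3a11, Cyp7a1, Sftpa1, Sftpb, Sftpc, Sftpd, Scgb1a1 and a gene that is not reported here. It also takes the 10 largest differences between tissues, and up to 5 rises and 5 falls between 10 and 5 mg/kg/day. The genes in the text are a subset of those the rule gave, picked after their values were seen.

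The fits were tested on simulated data made from the liver and lung values with 50 genes changed at each of 4 sizes. Of the genes changed by 1 on the log2 scale, limma called 50 in the liver comparison of 10 with 0 mg/kg/day, over 13269 genes, and 46 in that of lung, over 12897. Of the 50 genes changed by 0.3, it called 12 in liver and 18 in lung in the same comparisons. It also called 10 and 6 unchanged genes. In lung that simulation had 160 calls in all, against 7 in the measured data. More calls loosen the adjusted threshold, and the simulated noise was independent between genes. The shares of genes found therefore do not carry over to the measured lung values. The alternatives tried were no filter and a stricter filter on dim probe sets, other normalizations, array weights, other samples in the fit, other uses of several probe sets, another variance model, the replicate number as a block, the sex make-up of the pools as a covariate, and leaving out each litter. How often other divisions of the litters gave as many calls was counted over 100 splits. Probe sets without a single symbol were left out of the gene tests and tested apart.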

Results

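Transcript levels were measured in fetal lung and fetal liver of CD-1 mice, an outbred stock, after the dams were given perfluorooctane sulfonate (PFOS), a persistent fluorinated surfactant. There were 30 arrays, 15 per tissue, each of 1 litter, with 5 litters per tissue at each of 0, 5 and 10 mg/kg/day. The labels do not state whether both tissues came from the same litters. The comparisons ask which transcripts of each tissue differed with dose and whether the tissues responded differently. Arrays of the same group correlated with r from 0.990 to 0.995 across probe sets, which are not independent of each other. The number of litters limits the precision. Changes are log2 differences from the unexposed litters of the same tissue, with n = 5 litters per group, given for 5 and then 10 mg/kg/day where a pair of values stands.

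Genes of fatty acid oxidation rose in fetal liver at both doses. Ehhadh, a bifunctional enzyme of peroxisomal beta-oxidation, went from 9.37 ± 0.34 (SD, n = 5) without PFOS to 12.26 ± 0.24 at 5 mg/kg/day and 12.67 ± 0.26 at 10 mg/kg/day. Acaa1b, a peroxisomal thiolase, rose by 2.23 and 2.46, and the acyl-CoA thioesterases Acot3 and Acot4 rose by 2.32 and 2.66 and by 2.03 and 2.47. Of 22 tested peroxisomal beta-oxidation genes, 18 rose at 5 mg/kg/day, and 19 rose and 1 fell at 10 mg/kg/day. Adjusted over the list alone, 20 rose at the lower dose, and 20 rose and 2 fell at the higher. The change of Ehhadh was 2.90 (SE 0.16, limma adjusted p = 2.66e-08) and 3.30 (SE 0.16, adjusted p = 3.62e-09), higher than the control mean in 5 of 5 and 5 of 5 litters. The list's median change was 0.74 and 0.82. Camera gave the list an adjusted p = 7.63e-30 and 5.58e-28, and an adjusted p = 0.0237 and 0.0300 with an estimated correlation.

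Mitochondrial beta-oxidation genes rose with them. Of 19 tested, 14 and 15 rose, and 17 at each dose adjusted over the list alone. The thioesterase Acot2 rose by 2.50 and 3.29, the enoyl-CoA isomerase Eci1 by 1.14 and 1.37, and Cpt2, which moves acyl groups from carnitine to coenzyme A, by 1.03 and 1.27. The list's median change was 0.57 and 0.66 (camera adjusted p = 0.0221 and 0.0218 with an estimated correlation). Of 8 omega-oxidation genes, 4 rose at each dose, and 5 and 6 adjusted over the list alone. Among them the fatty acid omega-hydroxylase Cyp4a14 rose by 2.13 and 2.29, its relative Cyp4a12a by 1.34 and 1.72, and Aldh3a2, a fatty aldehyde dehydrogenase, by 1.07 and 1.28. The omega-oxidation list lost its call at 5 mg/kg/day with an estimated correlation (adjusted p = 0.0544) and kept it at 10 mg/kg/day (adjusted p = 0.0468).

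Lipid droplet and fatty acid handling genes rose in liver as well. Of 25 tested, 12 rose at each dose, and 15 at each adjusted over the list alone. The thioesterase Acot1 rose by 2.98 and 3.28, Pdk4, a kinase that inhibits pyruvate dehydrogenase, by 1.77 and 2.13, the pantetheinase Vnn1 by 1.52 and 1.68, and Plin2, a lipid droplet coat protein, by 0.91 and 1.18. The list had an adjusted p = 0.00961 and 0.00611 with an estimated correlation. Outside this list Fgf21, a hormone secreted by liver, rose by 0.99 at 5 mg/kg/day (limma adjusted p = 0.0132, higher in 5 of 5 litters) and had a change of 0.66 at 10 mg/kg/day (adjusted p = 0.0686, and 0.0471 without litter 2 at 10 mg/kg/day). Its adjusted p at 5 mg/kg/day was 0.178 without control litters 2, 3 and 5, at a change of 0.91, and at 10 mg/kg/day it was 0.0287 with the 2 groups alone and 0.0117 with both tissues in 1 fit.

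**Figure D1:**
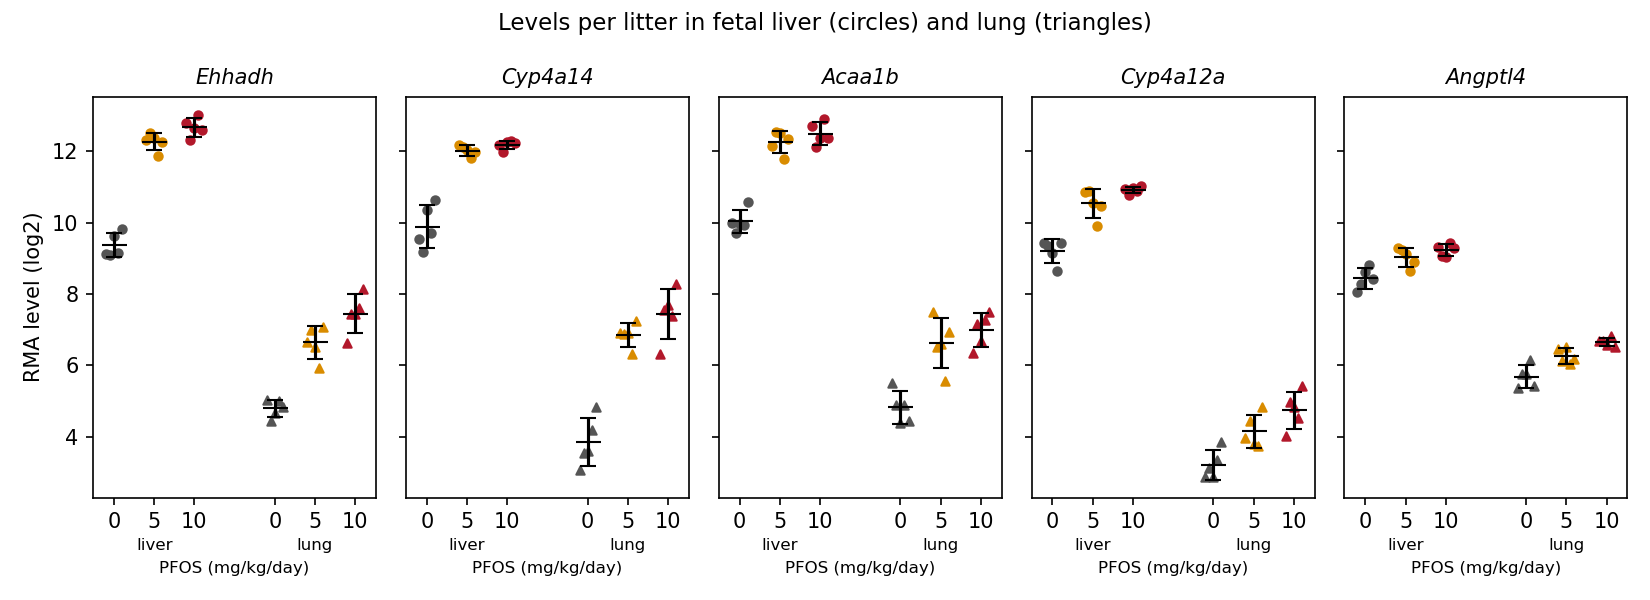
RMA level (log2, vertical axis) of 5 genes in each litter by PFOS dose (mg/kg/day, horizontal axis) in fetal liver (circles) and lung (triangles), with bars for the mean and SD of 5 litters. Mean Ehhadh was 9.37 in unexposed liver and 12.67 at 10 mg/kg/day, and 4.80 and 7.45 in lung.

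Genes of sterol and fatty acid synthesis also rose in liver. Of 20 cholesterol synthesis and uptake genes, 14 and 16 rose, and 16 and 17 adjusted over the list alone. Lanosterol synthase, Lss, rose by 0.91 and 1.06, and Hsd17b7, an enzyme of the same pathway, by 0.99 and 0.98. The list's call was lost with an estimated correlation (adjusted p = 0.102 and 0.111). Of 19 fatty acid and triglyceride synthesis genes, 10 rose at 5 mg/kg/day, and 11 rose and 1 fell at 10 mg/kg/day. Adjusted over the list alone, 14 rose at the lower dose, and 13 rose and 1 fell at the higher. The fatty acid desaturase Scd1 rose by 0.73 and 0.94. Acacb, an acetyl-CoA carboxylase, rose by 1.14 and 1.28 on its brighter probe set, while its other probe set had -0.10 at 10 mg/kg/day and their average 0.57 and 0.59. This list's call was lost too (adjusted p = 0.102 and 0.158 with an estimated correlation).

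Genes of xenobiotic metabolism rose in part. Cyp3a11, a drug-metabolising cytochrome P450, rose by 1.06 and 1.17, and the aldehyde dehydrogenases Aldh1a7 and Aldh1a1 rose by 2.32 and 2.68 and by 1.34 and 1.88. Of 26 targets of the nuclear receptors CAR and PXR, 6 rose and 1 fell at 5 mg/kg/day, and 12 rose and 2 fell at 10 mg/kg/day. Adjusted over the list alone, 13 rose and 2 fell at the lower dose, and 15 rose and 4 fell at the higher. Cyp2b10 had a change of 0.44 at 5 mg/kg/day (limma adjusted p = 0.137) and rose by 0.72 at 10 mg/kg/day (adjusted p = 0.00957, higher in 5 of 5 litters). Cyp2c29 had 1.80 at 5 mg/kg/day (adjusted p = 0.0655, and 0.00870 without litter 1 at 5 mg/kg/day) and rose by 2.45 at 10 mg/kg/day (adjusted p = 0.00852, higher in 5 of 5). The list's call was lost with an estimated correlation (adjusted p = 0.308 and 0.246). Without control litters 2, 3 and 5 the calls of Cyp2b10 and Cyp2c29 at 10 mg/kg/day were lost (adjusted p = 0.147 and 0.0511, at changes of 0.70 and 2.97), as with both tissues in 1 fit were those of Cyp2c29 (0.0808) and of Cyp3a11 at both doses (adjusted p = 0.279 and 0.182). That fit takes in the spread of the lung arrays. In lung at 5 mg/kg/day Cyp3a11 was 11.30 in litter 1 against a mean of 7.56 in the others. With its probe sets averaged the change of Cyp2b10 was 1.15 and 1.62. At 5 mg/kg/day it then passed (0.0306), as it did with the 2 groups alone (0.0326), and Cyp2c29 with a stricter filter (0.0481), array weights (0.0292) or a sex covariate (0.00684). Outside this list, microsomal epoxide hydrolase, Ephx1, rose by 1.23 and 1.48, malic enzyme, Me1, by 1.31 and 1.76, the chemokine Cxcl10 by 1.85 and 2.48, and the carboxylesterases Ces1e, Ces1f and Ces1g by 2.25 and 2.68, by 3.01 and 3.41 and by 2.19 and 2.69.

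Genes of bile acid synthesis and of secreted liver proteins were among those that fell. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a change of -0.65 (SE 0.22, limma adjusted p = 0.108) at 5 mg/kg/day and fell by 1.41 (SE 0.22, adjusted p = 0.000625) at 10 mg/kg/day, lower than the control mean in 5 of 5 litters. Slco1a1, an organic anion transporter, fell at both doses, with changes of -0.72 and -0.97. Of 17 bile acid genes, 1 and 4 fell, and 5 at each dose adjusted over the list alone. Camera called the list at 10 mg/kg/day, a call lost with an estimated correlation (adjusted p = 0.394). Of 44 complement, coagulation and plasma protein genes, 3 rose and 2 fell at 5 mg/kg/day, and 8 fell at 10 mg/kg/day. Adjusted over the list alone, 3 rose and 3 fell at the lower dose, and 1 rose and 13 fell at the higher. The mannose-binding lectin gene Mbl2 fell at both doses (-0.74 and -1.25), and Apoa5, an apolipoprotein, fell by 1.55 at 10 mg/kg/day. With both tissues in 1 fit the adjusted p was 0.407 and 0.0849 for Mbl2 and 0.0437 for Cyp7a1 at 5 mg/kg/day, and without control litters 2, 3 and 5 it was 0.0933 for Slco1a1 at 5 mg/kg/day, at a change of -0.78. The plasma protein list lost its call at 10 mg/kg/day (adjusted p = 0.370 with an estimated correlation).

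Other genes that fell in liver at both doses were on none of the fixed gene lists named above. Cyp39a1, an oxysterol hydroxylase, had changes of -0.95 and -1.64, Fhad1 of -1.38 and -1.61 and Lrtm1 of -1.17 and -1.64. Enho, which encodes the secreted peptide adropin, had -1.03 and -1.31 (-0.79 at 10 mg/kg/day with probe sets averaged), the glucokinase regulator Gckr -0.58 and -0.77, and the fetal growth factor Igf2 -0.34 and -0.32. Without control litters 2, 3 and 5 the calls at 5 mg/kg/day were lost for Cyp39a1, Lrtm1, Gckr and Igf2 (adjusted p = 0.0605, 0.0545, 0.216 and 0.109, at changes of -0.94, -1.16, -0.44 and -0.30) and at 10 mg/kg/day for Igf2 (0.107, at a change of -0.28). With both tissues in 1 fit they were lost for Gckr at 5 mg/kg/day (0.0621) and for Igf2 (0.0744 and 0.0748). Cym, which encodes the milk-clotting protease chymosin, had a change of -2.48 at 5 mg/kg/day (limma adjusted p = 0.111) and fell by 2.82 at 10 mg/kg/day (adjusted p = 0.04999, lower in 5 of 5 litters). Its level was 11.27, 9.50 and 8.20 in control litters 2, 3 and 5 against 5.05 and 5.28 in control litters 1 and 4. At 10 mg/kg/day the call was lost on leaving out 1 litter in 8 of 10 fits (adjusted p = 0.0989, 0.116 and 0.0927 without litters 2, 3 and 5 at 0 mg/kg/day and 0.0756, 0.0677, 0.0828, 0.104 and 0.0885 without litters 1, 2, 3, 4 and 5 at 10 mg/kg/day), and at 5 mg/kg/day the adjusted p was 0.0309 and 0.0358 without litters 1 and 4 at 0 mg/kg/day. Of 10 other settings, 8 lost the Cym call at 10 mg/kg/day (adjusted p = 0.0507 to 0.858), and both tissues in 1 fit gave 0.0235 at 5 mg/kg/day. Without control litters 2, 3 and 5 its change was 0.22 and -0.12.

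Cell cycle and blood cell genes fell in part in the fetal liver, a blood-forming organ. Of 35 cell cycle genes, 8 and 6 fell, and 23 and 10 adjusted over the list alone. The centromere protein gene Cenpf fell at both doses (-0.38 and -0.37). Of 32 erythroid genes, 5 fell at 5 mg/kg/day, among them Hemgn, which fell by 0.41, and 13 adjusted over the list alone. At 10 mg/kg/day limma called 0 of them over all genes and 0 adjusted over the list alone, among 3178 genes of the array with an unadjusted p under 0.05, and Hemgn had -0.20. Of 19 granulocyte genes, 6 fell at 10 mg/kg/day, and 13 adjusted over the list alone, among them the protease gene Prtn3, which fell by 0.41. The calls of these lists were lost with an estimated correlation (adjusted p = 0.314 and 0.402 for cell cycle, 0.314 for erythroid genes at 5 mg/kg/day and 0.370 for granulocytes at 10 mg/kg/day). Leaving out 1 litter ended the limma calls of Cenpf at 5 mg/kg/day (adjusted p = 0.0597 and 0.0509 without litters 1 and 2 at 0 mg/kg/day and 0.0607 and 0.0691 without litters 1 and 5 at 5 mg/kg/day) and of Prtn3 (adjusted p = 0.0538, 0.0655 and 0.0704 without litters 1, 3 and 4 at 0 mg/kg/day and 0.0728, 0.0594 and 0.0514 without litters 3, 4 and 5 at 10 mg/kg/day), and gave Hemgn at 10 mg/kg/day an adjusted p = 0.0443 without litter 2 at 10 mg/kg/day. Calls of Cenpf were lost without control litters 2, 3 and 5 (adjusted p = 0.161 and 0.136, with changes of -0.42 and -0.41), with probe sets averaged (0.169 and 0.476, with changes of -0.21 and -0.11) and with both tissues in 1 fit (0.132 and 0.117). Prtn3 had 0.133 without those litters, at a change of -0.48, Prtn3 and Hemgn at 5 mg/kg/day had 0.128 and 0.2999 with both tissues in 1 fit, and Hemgn at 10 mg/kg/day had 0.0440 after quantile normalization and 0.0497 with a trended and robust spread.

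In total, limma called 805 of 13269 liver genes at 5 mg/kg/day, 565 higher and 240 lower, and 1395 at 10 mg/kg/day, 703 higher and 692 lower. On leaving out 1 litter, the number lower was 148 without exposed litter 5 and 151 without control litter 2 at 5 mg/kg/day, and 455 without exposed litter 3 at 10 mg/kg/day. With all litters 468 genes rose and 183 fell at both doses, where independent lists would share 29.9 and 12.5. Both lists share the same controls, so they are not independent even without an effect of dose, and this overlap was not simulated. Across genes, which are not independent replicates, the changes at both doses correlated with r = 0.857. Unchanged groups sharing these controls gave 0.500 in simulation, and splitting the controls gave 0.647. The covariance was 0.0483 against 0.00705 simulated. The simulated genes varied independently of each other, which measured genes do not. Without control litters 2, 3 and 5, high in Cym and left out after the data were seen, 295 and 540 genes passed, 43 and 176 of them lower. Leaving out any other 3 controls gave 206 to 507 and 420 to 680 genes, so fewer controls alone give such counts.

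Between 10 and 5 mg/kg/day limma called 1 liver gene, Lims2, which encodes an adhesion adaptor. It fell by 0.58 (SE 0.08, adjusted p = 0.0273, lower in 5 of 5 litters), and 1035 genes had an unadjusted p under 0.05 where chance gives 663. Leaving out 1 litter ended the Lims2 call in 8 of 10 fits (adjusted p = 0.0803, 0.114, 0.125 and 0.102 without litters 2, 3, 4 and 5 at 5 mg/kg/day and 0.0781, 0.128, 0.146 and 0.139 without litters 1, 2, 3 and 5 at 10 mg/kg/day). The count was 2 without litter 1 at 5 mg/kg/day, 4 without litter 4 at 10 mg/kg/day and 0 without any 1 of the others. With both tissues in 1 fit Lims2 had an adjusted p = 0.0587.

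Fetal lung samples differed in few genes, among them Cyp4a14 and Ehhadh at both doses. Liver RNA in these samples may account for part or all of the rises of Cyp4a14, Ehhadh, Acaa1b and Cyp4a12a. It was not told apart from a response of lung cells. Cyp4a14 went from 3.85 ± 0.67 (SD, n = 5) without PFOS to 6.86 ± 0.33 at 5 mg/kg/day and 7.45 ± 0.71 at 10 mg/kg/day, and Ehhadh from 4.80 ± 0.23 to 6.64 ± 0.46 and 7.45 ± 0.54. At 10 mg/kg/day the thiolase gene Acaa1b rose by 2.17, Cyp4a12a by 1.53, and Angptl4, an inhibitor of lipoprotein lipase, by 0.97. The peptidase neprilysin, Mme, fell by 0.47 and Dlc1 fell by 0.29. Cyp4a14 rose by 3.01 (SE 0.33, limma adjusted p = 0.00163) and 3.60 (SE 0.33, adjusted p = 7.08e-05), and Ehhadh by 1.85 (SE 0.24, adjusted p = 0.00760) and 2.66 (SE 0.24, adjusted p = 7.08e-05). At 10 mg/kg/day the adjusted p was 0.0111 for Acaa1b, 0.00873 for Angptl4, 0.0406 for Mme, 0.0406 for Dlc1 and 0.04999 for Cyp4a12a, and 5 of 5 exposed litters lay on the stated side of the control mean for each of these genes. Acaa1b had 1.79 at 5 mg/kg/day (adjusted p = 0.132, 0.00773 without litter 4 at 5 mg/kg/day and 0.00114 with both tissues in 1 fit). The control means of Cyp4a14 and Cyp4a12a (3.21) lay below the 40th percentile of all probe sets, which was 4.16 to 4.22 on the lung arrays, and the other probe set of Angptl4 had -0.13. Leaving out 1 litter ended the calls of Acaa1b (adjusted p = 0.0555 without litter 3 at 0 mg/kg/day and 0.0509 without litter 5 at 10 mg/kg/day), Cyp4a12a (adjusted p = 0.196, 0.191, 0.176 and 0.102 without litters 1, 2, 3 and 4 at 0 mg/kg/day and 0.139, 0.163, 0.0944 and 0.113 without litters 2, 3, 4 and 5 at 10 mg/kg/day), Mme (adjusted p = 0.0959, 0.140, 0.102 and 0.112 without litters 1, 3, 4 and 5 at 0 mg/kg/day and 0.115, 0.0944 and 0.109 without litters 2, 4 and 5 at 10 mg/kg/day) and Dlc1 (adjusted p = 0.145, 0.107, 0.139 and 0.102 without litters 1, 2, 3 and 4 at 0 mg/kg/day and 0.0681, 0.163, 0.0699 and 0.113 without litters 2, 3, 4 and 5 at 10 mg/kg/day). Of 12 other settings, 9 ended the call of Mme (adjusted p = 0.0547 to 0.594), 9 of 12 that of Dlc1 (0.0521 to 0.411) and 10 of 11 that of Cyp4a12a (0.0502 to 0.207). Acaa1b had an adjusted p = 0.0516 with the cardiac muscle level as a covariate, at a change of 2.12, and Ehhadh had 0.0707 at 5 mg/kg/day without litter 1 of the 0 and 5 mg/kg/day groups, at a change of 1.90.

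In total limma called 2 of 12897 lung genes at 5 mg/kg/day, Cyp4a14 and Ehhadh, and 7 at 10 mg/kg/day. At an unadjusted p under 0.05 there were 596 and 891 genes, where chance gives 645. The lung arrays also held liver transcripts: Afp, a fetal plasma protein made by liver, ranged from 8.29 to 11.74 over the 15 lungs. It ran from 8.29 to 11.20 without PFOS, from 9.63 to 11.51 at 5 mg/kg/day and from 10.17 to 11.74 at 10 mg/kg/day. The lowest values at 0 and 5 mg/kg/day were those of litter 1. Without them Afp ran from 9.91 to 11.20 and from 10.90 to 11.51. Yet these 2 lungs had the highest means of the fixed list of liver transcripts, 9.28 and 9.62. Afp alone therefore does not rank the lungs by liver transcripts. In the lung of litter 1 at 0 and at 5 mg/kg/day Serpina6, the corticosteroid-binding globulin, was at 10.94 and 10.26, against a mean of 4.01 in the others. Without these 2 arrays 1 and 5 genes passed, and the adjusted p was 0.0707 for Ehhadh at 5 mg/kg/day and 0.107 for Mme, 0.180 for Dlc1 and 0.207 for Cyp4a12a at 10 mg/kg/day. Their changes without these arrays were 1.90, -0.47, -0.28 and 1.45, against 1.85, -0.47, -0.29 and 1.53 with them. The count at 10 mg/kg/day was 4, 3 and 4 without control litters 1, 3 and 4, and 11 and 3 without exposed litters 1 and 5.

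**Figure D2:**
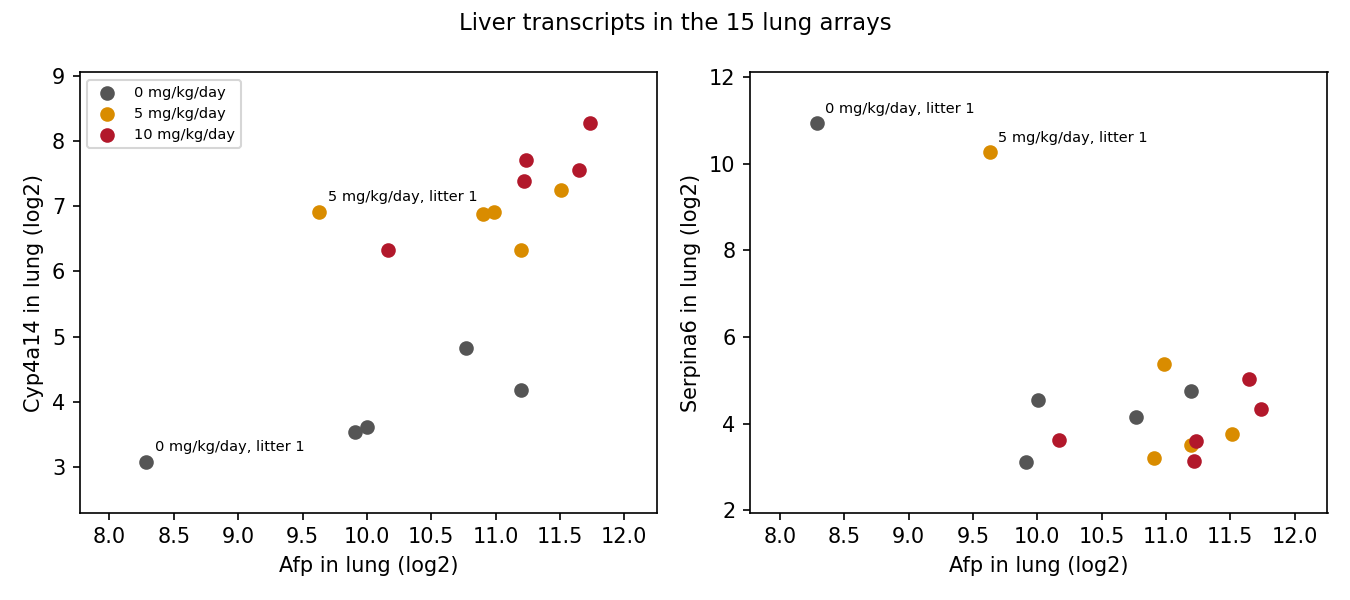
Level of Cyp4a14 (left) and Serpina6 (right) against that of Afp (all RMA log2) in each of the 15 lung arrays, coloured by PFOS dose. Serpina6 was at 10.94 and 10.26 in litter 1 at 0 and 5 mg/kg/day.

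As groups, oxidation genes shifted upwards in lung by small amounts. Of 6 omega-oxidation genes, 1 and 2 rose, and 2 and 3 adjusted over the list alone, with an adjusted p = 0.0408 and 0.0368 with an estimated correlation. Of 21 peroxisomal genes, 1 and 2 rose, and 6 at each dose adjusted over the list alone (adjusted p = 0.0944 and 0.0802 with an estimated correlation). The members of both lists called over all genes were Cyp4a14, Ehhadh, Acaa1b and Cyp4a12a. Liver RNA in the lung samples may account for part or all of their rises. These lists therefore do not tell a response of lung cells from liver RNA. Of 19 mitochondrial beta-oxidation genes limma called 0 at 10 mg/kg/day and 15 adjusted over the list alone, with a median change of 0.25 (camera adjusted p = 8.51e-19, and adjusted p = 0.0802 with an estimated correlation); 891 genes of the array had an unadjusted p under 0.05, where chance gives 645. Muscle markers also had positive median changes at 10 mg/kg/day. The 19 cardiac muscle genes had median changes of -0.07 and 0.83, and their mean level was 7.01 ± 0.90 (SD, n = 5) without PFOS, 6.93 ± 0.86 at 5 mg/kg/day and 7.82 ± 1.16 at 10 mg/kg/day. The 11 skeletal muscle genes had median changes of 0.60 and 0.63. With an estimated correlation the adjusted p was 0.599 for cardiac muscle at 10 mg/kg/day and 0.464 and 0.526 for skeletal muscle.

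**Figure D3:**
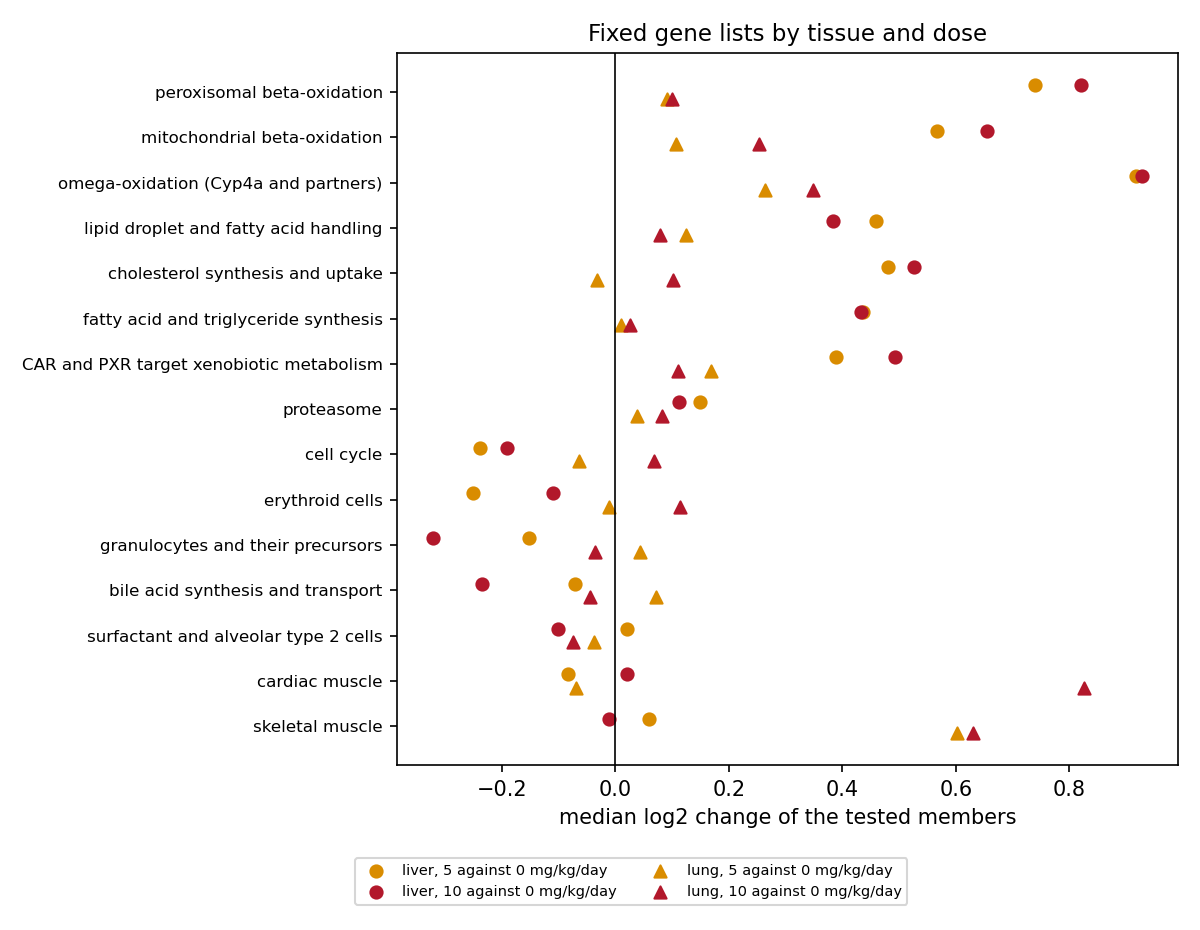
Median log2 change (horizontal axis) of the tested members of 15 fixed gene lists against 0 mg/kg/day, by tissue (circles for liver, triangles for lung) and dose (colours). Peroxisomal beta-oxidation genes had medians of 0.74 and 0.82 in liver and 0.09 and 0.10 in lung.

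Single surfactant and airway secretory genes did not pass the limma test in lung at either dose. At 10 mg/kg/day the surfactant protein genes Sftpa1, Sftpb and Sftpd had changes of -0.29, -0.28 and -0.29 (limma adjusted p = 0.769, 0.726 and 0.778). Sftpc had -0.01 (adjusted p = 0.987), and 0.02 after quantile normalization of the lung arrays. The club cell secretory protein gene Scgb1a1 had -0.06 (adjusted p = 0.917), and 0.02 without exposed litter 2. Of 23 surfactant and alveolar type 2 genes limma called 0, and 0 adjusted over the list alone, among 891 genes of the array with an unadjusted p under 0.05. The list's median was -0.08 (camera adjusted p = 0.00296, and adjusted p = 0.575 with an estimated correlation). Of 15 club and secretory cell genes limma called 0 at each dose, and 0 adjusted over the list alone, among 596 and 891 genes of the array with an unadjusted p under 0.05. Their median changes were 0.09 and 0.07 (camera adjusted p = 0.0361 and 0.140), and the call at 5 mg/kg/day was lost with an estimated correlation (adjusted p = 0.779). Cyp3a11 had 1.94 in lung (adjusted p = 0.594, and 0.00470 without the 2 arrays high in Serpina6), Cyp2b10 0.16 and Pdk4 0.47.

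Between 10 and 5 mg/kg/day limma called 0 lung genes, and 296 had an unadjusted p under 0.05 where chance gives 645. The count was 1 without litter 3 at 5 mg/kg/day. The lung changes at both doses correlated across genes, which are not independent replicates, with r = 0.656, against 0.501 in simulation with no effect and 0.163 with split controls. The covariance was 0.0120 against 0.00803 simulated. The simulated genes varied independently, unlike genes that share liver or muscle content across the lung arrays. How far r can lie from 0.501 without an effect of dose is therefore unknown.

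The changes of liver and lung differed in single genes. At 10 mg/kg/day Acot2 had a change of 3.29 in liver and 0.18 in lung, a difference of 3.11 (SE 0.21, limma interaction adjusted p = 7.78e-11). The liver minus lung differences were 2.75 for Acot1, 2.68 for Aldh1a7, 2.32 for Acot3, 2.27 for the lectin gene Lgals2, 2.00 for the water and glycerol channel Aqp3, 1.96 for the phospholipid transfer protein gene Pltp, and 1.90 for the leptin receptor gene Lepr. In total 260 of 12310 genes differed at 5 mg/kg/day and 500 at 10 mg/kg/day, with the larger change in liver for 252 and 481 of them. Across genes, which are not independent replicates, the changes of both tissues correlated with r = 0.230 and 0.220. No value for tissues without a shared response was computed. Liver RNA in the lung samples, or litters shared by both tissues, could raise r without such a response.

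Of the fixed gene lists, camera called 15 of 51 in liver at 5 mg/kg/day and 18 at 10 mg/kg/day, and 13 and 16 of 50 in lung. With an estimated correlation 3 and 4 lists passed in liver, those of peroxisomal and mitochondrial beta-oxidation and of lipid droplets at both doses and omega-oxidation at 10 mg/kg/day, and 1 at each dose in lung, omega-oxidation. Its called members in lung, Cyp4a14 and at 10 mg/kg/day also Cyp4a12a, are among the genes whose rises liver RNA may account for.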

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

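Of the tests in this part, those of liver RNA behind the lung genes and of fetal liver RNA in a pair of lung arrays were chosen after the results were seen, and leaving out those arrays and the cardiac covariate were alternatives added after seeing the data.

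Genes with high levels in liver rose in lung at 10 mg/kg/day (Cyp4a14, Ehhadh, Acaa1b and Cyp4a12a). Liver RNA in the lung samples may account for part or all of this, since these genes also rose in liver. It cannot be told apart from a response of lung cells to PFOS, which stays open and untested. The liver array of the same dose and number stood for each litter. The liver share was set from transcripts with little difference between doses in liver. The lung arrays of litter 1 at 0 and 5 mg/kg/day were left out. Observed minus predicted change had a median of -0.0490, with Ehhadh at 0.01 (SE 0.27) and Acaa1b at -0.11 (SE 0.25). Each SE is that of the observed change alone and leaves out the error of the prediction. Cyp4a14 at 0.90 (SE 0.44) and Cyp4a12a at -0.68 (SE 0.31) lay over 2 SE to either side of the prediction, but their control means lay below the 40th percentile of all probe sets, so that they exclude nothing. For Angptl4 0.703 (SE 0.16) was left unpredicted, on 1 of its 2 probe sets. This argues against liver RNA as the whole source only if the share used holds. The share was uncertain, with quartiles over its transcripts of 1.63% and 5.49% in litter 4 at 10 mg/kg/day. Over 9 exposed lung arrays within doses, the mean of the 4 genes and Afp gave r = 0.769 (exact permutation p = 0.0372) and rho = 0.600 (exact permutation p = 0.108), but r = 0.310 without the 2 farthest arrays, so the relation rests on those.

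Lung arrays of litter 1 at 0 and at 5 mg/kg/day held Serpina6 at 10.94 and 10.26, above the highest fetal liver array (9.16), while their Afp (8.29 and 9.63) lay under the mean of the other lungs (10.96). Genes were counted that lay, in both, over 0.5 above every fetal liver array and over 2 above the mean of the other lungs. The count was 1, Serpina6, between the bounds set for and against fetal liver RNA, so the count does not decide. Cyp2c29 was at 8.84 and 10.30 in these lungs, against 4.11 and 5.46 in the livers of the same dose and number. The highest liver of the same dose had 6.18 and 8.85, but the liver of litter 1 at 10 mg/kg/day had 9.43. A mix cannot exceed its source. For Serpina6 and Cyp2c29, picked after their values were seen, this argues against fetal liver RNA of the same dose as the whole source. The plasma protein genes Hpx, Alb and Apoa1 were at 9.80 and 9.68, 13.11 and 13.17, and 10.38 and 10.72 in these lungs. The livers of the same dose and number had 11.71 and 11.66, 13.85 and 13.83, and 13.39 and 13.37, with Afp at 12.71 and 12.88. Against those livers, Afp lay further below than Hpx, Alb or Apoa1 in both lungs. For these genes this argues against fetal liver RNA as the whole source, which would bring more Afp. For the remaining transcripts of these arrays fetal liver RNA stays open. Adult liver RNA stays open: 17 measured adult liver genes exceeded the other lungs by a median of 0.761, between the bounds set for and against it, 5 of them by over 1, and 0 of them lay above every fetal liver array in both. No biological explanation was tested, since the arrays belong to different doses.

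Mitochondrial beta-oxidation genes had a median change of 0.25 in lung at 10 mg/kg/day, where cardiac muscle genes had a median change of 0.83. With the cardiac mean as a covariate the median was 0.195 (camera unadjusted p = 5.72e-14 at the preset correlation), which met the bound set against heart tissue as the whole cause. This is weak evidence. Camera at that correlation called as many lists as at the real doses in 24 of 100 splits of the lung litters, the real one included. With an estimated correlation the unadjusted p was 0.00642 without and 0.0176 with the covariate, but adjusted over all lists the former was 0.0802, so the pattern itself does not pass there. Liver RNA predicted a median of 0.105, between the bounds set for and against it, so it stays open as a partial source. A response of the lung to PFOS stays open and untested.

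Other divisions of the litters were counted over 100 splits, the real one included. Only the real split gave as many genes in liver at 5 mg/kg/day (805 genes, as many in 1 split, highest other 106) and 10 mg/kg/day (1395, in 1, highest other 61). The same held in lung at 5 mg/kg/day (2, in 1, highest other 1, with 596 genes at an unadjusted p under 0.05 where chance gives 645) and 10 mg/kg/day (7, in 1, highest other 3). In lung at 5 mg/kg/day the counts of 2 and 1 are too close to decide. The other splits mix exposed and control litters, so a real effect widens their spread and lowers their counts. For the genes differing between tissues, too, only the real split gave as many at 5 mg/kg/day (260, in 1, highest other 3) and 10 mg/kg/day (500, in 1, highest other 1). With 100 splits no share under 1 in 100 can be seen. Chance is not excluded for the comparison of 10 with 5 mg/kg/day in liver (1 gene, as many in 5 splits, highest other 1). For lung the same comparison had 0 genes by limma (296 at an unadjusted p under 0.05), so that all 100 splits give as many and the count tests nothing (highest other 10). Chance is also not excluded for the number of gene lists called by camera with the preset correlation, in liver at 5 mg/kg/day (15, as many in 20, highest other 23) and 10 mg/kg/day (18, in 13, highest other 25) and in lung at 5 mg/kg/day (13, in 38, highest other 19) and 10 mg/kg/day (16, in 24, highest other 25).

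The changes of liver and lung differed by a test of the difference itself in 260 genes at 5 mg/kg/day and 500 at 10 mg/kg/day. Probe sets without a single gene name, which no comparison of genes used, were called in lung (1 and 2 of 4361) and in liver (136 and 226 of 4284) at 5 and 10 mg/kg/day.

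A litter lay far from the other 4 of its group, by its gap over the range, in 16 of 225 pairs of gene and group, where chance gives about 5 in 100. Cyp3a11 in lung at 5 mg/kg/day was 11.30 in litter 1 against a mean of 7.56 in the others (ratio 0.713) and Scgb1a1 in lung at 5 mg/kg/day was 12.70 in litter 4 against a mean of 12.89 in the others (ratio 0.807). Sftpa1 in lung at 0 mg/kg/day was 11.30 in litter 5 against a mean of 11.89 in the others (ratio 0.733) and Apoa5 in liver at 0 mg/kg/day was 10.68 in litter 3 against a mean of 9.64 in the others (ratio 0.794). Apoa5 in liver at 5 mg/kg/day was 9.62 in litter 5 against a mean of 9.10 in the others (ratio 0.848) and Azgp1 in liver at 0 mg/kg/day was 9.70 in litter 1 against a mean of 9.08 in the others (ratio 0.770). Cenpe in liver at 10 mg/kg/day was 7.48 in litter 2 against a mean of 7.16 in the others (ratio 0.796) and Cym in liver at 10 mg/kg/day was 4.23 in litter 4 against a mean of 5.24 in the others (ratio 0.730). Cyp2c29 in liver at 0 mg/kg/day was 4.11 in litter 1 against a mean of 6.06 in the others (ratio 0.888) and Enho in liver at 0 mg/kg/day was 7.69 in litter 1 against a mean of 7.99 in the others (ratio 0.713). Fhad1 in liver at 5 mg/kg/day was 3.71 in litter 3 against a mean of 4.64 in the others (ratio 0.802) and Klf1 in liver at 10 mg/kg/day was 10.72 in litter 2 against a mean of 10.30 in the others (ratio 0.787). Lss in liver at 0 mg/kg/day was 8.97 in litter 4 against a mean of 9.31 in the others (ratio 0.776) and Mbl2 in liver at 5 mg/kg/day was 8.71 in litter 1 against a mean of 9.47 in the others (ratio 0.908). Slc37a4 in liver at 5 mg/kg/day was 9.72 in litter 2 against a mean of 10.11 in the others (ratio 0.850) and Tdo2 in liver at 5 mg/kg/day was 5.34 in litter 4 against a mean of 6.85 in the others (ratio 0.840).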

How the results depend on the processing

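The alternatives without the 2 lung arrays rich in liver transcripts, without the 3 control livers high in Cym, and with the cardiac covariate were chosen after seeing the data. Of 1389 values of 120 called changes under alternatives other than leaving out 1 litter, 1272 kept direction and call, 117 lost the call and 0 turned; on leaving out 1 litter it was 1183, 117 and 0 of 1300. Of 39 changes not called, 27 of 482 values gained a call and 6 turned, and 12 and 6 of 390 on leaving out 1 litter. Of the called changes, 0 values moved by over 1.5 times on leaving out 1 litter, 0 with both tissues in 1 fit and 16 under other alternatives. Both tissues in 1 fit, the filters, the 2 groups alone, another variance model and the replicate block leave the size of a change as it is. Under these no value could move or turn, and only the call could change. Both tissues in 1 fit brings the spread of the other tissue into each test. Where no cause is named below, the cause was not tested. The number of arrays and dim signal limit what can pass.

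In lung, 10 with 0 mg/kg/day (7 in the report), limma called 4 without the filter, after quantile normalization, with array weights, with the replicate block and with the sex covariate, 3 with probe sets averaged and with the cardiac covariate and 13 with both tissues in 1 fit. In lung, 5 with 0 mg/kg/day (2 in the report), limma called 4 with both tissues in 1 fit and 1 without the 2 lung arrays. In liver, 10 with 5 mg/kg/day (1 in the report), limma called 0 with all probe sets and with the replicate block and 6 with both tissues in 1 fit. Both counts of 0 stood beside 2000 probe sets and 1043 genes with an unadjusted p under 0.05. In liver, 5 with 0 mg/kg/day (805 in the report), limma called 295 without the 3 controls. In liver, 10 with 0 mg/kg/day (1395 in the report), limma called 540 without the 3 controls. With all probe sets 894 and 1124 probe sets were higher in liver (565 and 703 genes in the report). Leaving out other triples of controls gave 206 to 507 and 420 to 680 genes, so fewer controls alone give such counts. With an estimated correlation 1 and 1 lists passed in lung and 3 and 4 in liver. The dose correlation was 0.163 in lung and 0.647 in liver with split controls, which removes what shared controls add, and 0.826 in liver without the filter.

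On leaving out 1 litter, liver 10 with 5 genes ran from 0 to 4, liver dose correlation ran from 0.825 to 0.866, lung 10 with 0 genes ran from 3 to 11, lung 10 with 5 genes ran from 0 to 1 and lung dose correlation ran from 0.549 to 0.703. Of values that turned sign, Sftpc in lung at 10 mg/kg/day was 0.0229 after quantile normalization, 0.00827 with the cardiac covariate and -0.0178 to 0.00348 on leaving out 1 litter. At 5 mg/kg/day it was -0.0178 with probe sets averaged, -0.00808 without the 2 lung arrays and -0.00173 to 0.0256 on leaving out 1 litter. Scgb1a1 ran -0.0288 to 0.0521 at 5 mg/kg/day and -0.119 to 0.0173 at 10 mg/kg/day. Without the 3 controls, liver Cym and Mug1 had 0.215 and 0.0251 at 5 mg/kg/day.

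With the replicate number as a block, limma called 2, 4 and 0 genes in lung (5 with 0, 10 with 0, 10 with 5 mg/kg/day) and 726, 1200 and 0 in liver, and camera 13 and 17 and 16 and 19 lists. The 0 in lung and in liver stood beside 301 and 1043 genes with an unadjusted p under 0.05. Of the called changes of single genes followed over the alternatives, the block ended these (adjusted p in brackets): lung Acaa1b 10 with 0 (0.0646), lung Mme 10 with 0 (0.109), lung Dlc1 10 with 0 (0.177), liver Aldh1a1 5 with 0 (0.0518), liver Cenpf 5 with 0 (0.0509), liver Cenpe 5 with 0 (0.0790), liver Mug1 10 with 0 (0.0754), liver Cym 10 with 0 (0.0509), liver Cenpe 10 with 0 (0.0535), liver Ltf 10 with 0 (0.0630) and liver Lims2 10 with 5 (0.0963). It added calls of liver Tdo2 5 with 0 (0.0370) and liver Azgp1 5 with 0 (0.0321). The numbers do not pair samples across doses: 3 of 15 lung pairs and 4 of 15 liver pairs correlated over 0.1. Between tissues, 12 of 15 pairs of 1 number did, 12 lungs matched their own number best, and Y-linked minus Xist levels gave r = 0.988 and rho = 0.929 (permutation p = 1e-05, the smallest possible; r = 0.981 without the 2 farthest litters), a hint of shared litters that the labels do not state. With the litter as a random block 336 and 660 genes differed between tissues.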

Other observations

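Of the tests in this part, those without control litters 2, 3 and 5 were chosen after the results were seen.

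Protein quality control genes rose in part in liver. Of 30 proteasome genes, 5 and 7 rose, and 18 and 10 adjusted over the list alone, among them Psmd4, a ubiquitin receptor of the proteasome, which rose by 0.37 and 0.49 (limma adjusted p = 0.00266 and 0.000131, higher in 5 and 5 of 5 litters). Of 11 heat shock genes, 3 rose at each dose, and adjusted over the list alone 4 rose and 1 fell at 5 mg/kg/day and 3 rose at 10 mg/kg/day. Both calls by camera were lost with an estimated correlation (adjusted p = 0.308 and 0.370 for the proteasome and 0.308 and 0.241 for heat shock). Gluconeogenesis and glycogen genes fell in part: of 14, 1 rose and 1 fell at 5 mg/kg/day and 3 fell at 10 mg/kg/day, with 7 that fell adjusted over the list alone at the higher dose. Psmd4 at 5 mg/kg/day had an adjusted p = 0.0624 without control litters 2, 3 and 5, at a change of 0.37, and a change of 0.23 with probe sets averaged. Gckr was among those that fell, with changes of -0.58 and -0.77 (adjusted p at 5 mg/kg/day = 0.216 without those litters, at a change of -0.44, and 0.0621 with both tissues in 1 fit), and the list's call at 10 mg/kg/day was lost (adjusted p = 0.141 with an estimated correlation).

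Markers of connective tissue cells fell in part in liver at 10 mg/kg/day. Of 14 stellate cell and fibroblast genes, 3 fell, and adjusted over the list alone 7 fell and 1 rose, with a median of -0.26. Of 27 mesenchyme and matrix genes, 5 fell and 1 rose, and adjusted over the list alone 12 fell and 1 rose, with a median of -0.25. Among the stellate cell genes Reln, an extracellular glycoprotein, fell at both doses (-0.28 and -0.44, limma adjusted p = 0.00728 and 9.36e-05, lower in 5 and 5 of 5 litters). At 5 mg/kg/day its adjusted p was 0.0535 without control litters 2, 3 and 5, at a change of -0.33, 0.298 with probe sets averaged and 0.110 with both tissues in 1 fit. Averaged, its changes were -0.12 and -0.25. In lung at 10 mg/kg/day 42 respiratory chain genes had a median change of 0.11, in arrays where cardiac muscle genes had a median change of 0.83. The adjusted p of these lists with an estimated correlation was 0.370 for stellate cells, 0.375 for mesenchyme and 0.619 for the respiratory chain.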
